A study of Homo sapiens with 6 samples.

How the data were processed

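RNA sequencing libraries from H1 human embryonic stem cells were analysed. The cells carried a doxycycline-inducible DUX4 construct and, per the labels, were transfected with antisense oligonucleotides (ASOs). The ASOs were a control (Ctrl_KD) or were directed at dup_161 (dup_161_KD) or dup_2477 (dup_2477_KD), which the series title describes as single copies of MLT2A1, a long terminal repeat subfamily. Per the labels, doxycycline at 1 µg/ml was added 24 h after transfection, and RNA was taken 24 h later. The 3 groups held 2 libraries each, 6 in all, made with a polyA-selecting kit that does not keep strand. Reads of overlapping genes on opposite strands can therefore not be told apart. The columns named NC in the deposited tables were read as the Ctrl_KD libraries.

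The authors deposited a table of read counts and a table of TPM values (transcripts scaled to a total of 1000000) for the same 6 libraries, over genes and repeat subfamilies together. The deposited counts were whole numbers, and the deposited TPM columns each summed to 1000000. Counts divided by TPM differed between libraries by 1 factor per library, up to 1.16 relative to Ctrl_KD replicate 1. Over the 31278 features with counts in all 6 libraries this factor varied by at most 4.9e-05%, so the authors' TPM fits a count divided by a fixed length and rescaled. The submitters' processing notes list FastQC 0.11.9, cutadapt 4.1, STAR 2.7.10a, featureCounts 2.0.1 and edgeR 3.30.3, with the genome builds GRCh38 and hg38. The role of each tool, the gene annotation and the treatment of reads with several alignments are not given in the sources used here. Coordinates are from GENCODE 29 on GRCh38, which held 55487 of the 60642 gene symbols (91.5%). It is not known whether the authors counted on that release.

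The count table held 61822 features, 60642 genes and 1180 repeat subfamilies. Repeats were counted per subfamily, so no value belongs to the targeted copies, whose positions are not given in the sources used here. Totals ran from 42373831 to 47659365 counts per library. A count of 0 allows up to 3 counts, which was taken as the floor over a group. Such limits cover counting error only, and only that of the group at the floor, since the counts of the other group were taken as observed.

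Differential expression was tested with edgeR 4.0.16 in R 4.3.3. Features were kept by filterByExpr with a minimum count of 10, which left 26964 genes and 1133 repeat subfamilies. TMM factors were computed over genes and repeats together. A single quasi-likelihood model with 1 mean per group was fitted to all 6 libraries, with 3 residual and 26.3 prior degrees of freedom and a common biological coefficient of variation of 4.61%. Each knockdown was compared with Ctrl_KD, and dup_161_KD was compared directly with dup_2477_KD. P-values were adjusted by the Benjamini-Hochberg method, over genes and over repeats separately, and an adjusted p under 0.05 was called. The word repeat below means a subfamily of transposable elements or satellites. Standard errors (SE) are the absolute log2 fold change divided by the square root of the F statistic. Levels are CPM, counts scaled to a library total of 1000000 with TMM factors, given as the mean ± SD of 2 libraries.

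Gene lists were fixed before the data were examined: 21 lists of genes and 5 of repeats. The gene lists were 8-cell and DUX4 target genes, primed pluripotency, naive pluripotency, p53 targets, integrated stress response and unfolded protein response, heat shock response, interferon response, immediate early genes, cell cycle and proliferation, cytosolic ribosomal proteins, mitochondrially encoded proteins, nuclear oxidative phosphorylation, glycolysis and hypoxia, cholesterol biosynthesis, heterogeneous nuclear ribonucleoproteins, RNA polymerase II subunits and general transcription factors, retroelement repression, and markers of trophoblast, mesendoderm and endoderm, neuroectoderm and fibroblasts. The repeat lists were MLT2 and ERVL elements, THE1, MST and MLT1 elements, HERVH and HERVK elements, young LINE-1, SVA and AluY elements, and satellite repeats. Each list was tested with camera from limma 3.58.1 with a preset correlation of 0.01, adjusted over the 26 lists of a comparison, then with an estimated correlation and with fry. A list is said to pass by camera at the preset correlation unless another test is named. Counts of members are adjusted over all features tested, and counts adjusted over the list alone are given where they differ. Some genes stand in more than 1 list; 2 genes are in both the 8-cell and naive lists, and 2 are in both the primed and retroelement lists.

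The rule for naming genes was also fixed before the data were examined. For each knockdown against Ctrl_KD it took the 8 genes higher and the 8 lower with the largest fold changes among those called, with a mean of at least 5 CPM in the higher group and with both knockdown libraries beyond both control libraries. For the direct contrast it took 6 each way. Clone-based gene names were counted and not named. The rule added up to 3 called members of each list by smallest p, the 3 most abundant members of the 8-cell and primed lists, and the 4 repeats in each direction with the smallest p. DUX4, HNRNPU, MLT2A1, MLT2A2 and HERVL-int were named whatever their p. Results for some genes that this rule takes are not reported here.

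The pipeline was tested on simulated data in which 100 genes were changed at each of 2 fold sizes, in a single data set per comparison. In the real data 34.7% to 45.2% of genes were called, a far larger share, and adjusted p-values depend on that share. The recovery and false calls below therefore hold for the simulated setting only. For dup_161_KD against Ctrl_KD, with 26239 genes tested, it recovered 42% of the genes changed by 0.5 on the log2 scale and 71% of those changed by 1, with 1.74% of calls false. For dup_2477_KD against Ctrl_KD, with 26257 genes tested, it recovered 52% and 70%, with 5.43% of calls false. For dup_161_KD against dup_2477_KD, with 26235 genes tested, it recovered 51% and 65%, with 0.855% of calls false.

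The alternatives fixed before the data were examined included RLE size factors, DESeq2 1.42.0, no filter on low counts, at least 1 CPM in at least 2 libraries, scaling from genes alone, only the 4 libraries of a comparison, limma on log2 TPM with a pseudocount of 1 or of 0.1 for features with a mean TPM of at least 0.5, a minimum fold of 2, and each library left out in turn. Offsets for GC content and length were added after seeing the data, and 94.5% of the genes tested had both values. Under the alternatives, lists were tested by camera at the preset correlation, in edgeR fits to all 6 libraries or with 1 left out. Ranges over the alternatives given for lists cover those fits only. They leave out DESeq2, limma on log2 TPM, the fits of 4 libraries and the estimated correlation. The labels do not say whether the 2 libraries of a group came from separate cultures.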

Results

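Expression was measured by polyA RNA sequencing in H1 human embryonic stem cells in which doxycycline induced DUX4, the transcription factor that switches on genes of the 8-cell embryo. ASOs against dup_161 or dup_2477, single copies of the MLT2A1 repeat, were compared with a control ASO, in 2 libraries per group. The libraries held 42373831 and 45379388 counts in Ctrl_KD, 46526335 and 47659365 in dup_161_KD, and 46659557 and 46698062 in dup_2477_KD. Repeats took between 16% and 17.2% of the counts. Mitochondrially encoded genes took 4.15% and 4.01% of gene counts in Ctrl_KD, 4.51% and 4.31% in dup_161_KD, and 5.07% and 5.04% in dup_2477_KD. The leading axis of variation (54.8%) set both knockdowns apart from Ctrl_KD, and the next one (22.4%) separated dup_161_KD from dup_2477_KD. Across genes, which are not independent replicates, log2 levels of the 2 libraries of a group correlated with Pearson r from 0.9972 to 0.998.

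The question of the series was which genes and repeats change when a single MLT2A1 copy is knocked down. After dup_161 knockdown, RNA of DUX4 and of 61 of the 70 8-cell genes tested was lower than in Ctrl_KD, and so was MLT2A1. DUX4 fell from 141.5 ± 15.4 CPM to 2.666 ± 0.355 CPM (SD, n = 2), which is 53-fold. SLC34A2, a phosphate transporter gene that DUX4 switches on, fell from 215.2 to 36.16 CPM, and KLF17, a transcription factor of the early embryo, fell from 21.33 to 2.741 CPM. The extracellular matrix gene COL1A2 rose from 138.8 to 625.4 CPM. Of 26964 genes tested, 5796 were higher and 5817 were lower (43.1% together), among them 1298 higher and 1522 lower by at least 2-fold. Of 1133 repeat subfamilies, 68 were higher and 321 lower. These p-values measure only the spread between the libraries of a group, which may be technical.

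DUX4 lies on chromosome 4 at 190173774 to 190185942 (GRCh38) and had a log2 fold change of -5.73 (SE 0.09, adjusted p = 1.46e-28). Whether reads of the induced construct are counted in this gene is not known, and construct and endogenous copies were not separated. The ASO sequences are not given in the sources used here, so it is also not known whether they match transcripts that hold DUX4. Related copies fell with it, DUX4L2 (-8.90), DUX4L7 (-8.02), DUX4L12 (-7.63) and DUX4L8 (-5.28). DUX4L22 had 1572 counts in Ctrl_KD and 2 in dup_161_KD. DBET, a noncoding RNA of the DUX4 repeat array, had 638 counts in Ctrl_KD and 0 in dup_161_KD, at least 230-fold lower against a floor of 3 counts over the group. The sum over 42 DUX4 and DUX4L genes was 47.1-fold lower. PRR23D1 (chromosome 8, 7539628 to 7542450), the remaining gene among the 8 largest falls, fell by 5.51.

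**Figure D1:**
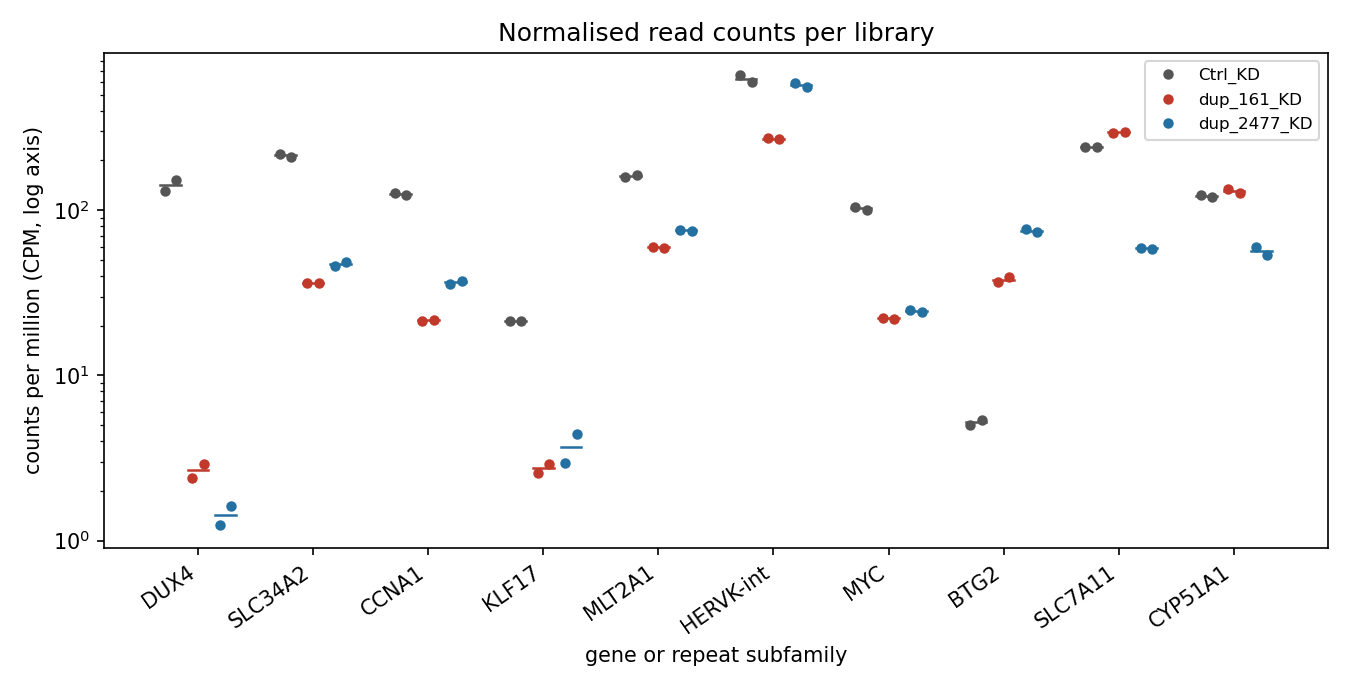
CPM (log axis) of 8 genes and 2 repeat subfamilies in each library, with points for the 2 libraries of a group and lines for the group means. DUX4 lies at 131 and 152 CPM in the Ctrl_KD libraries and at no more than 2.92 CPM in any knockdown library, while HERVK-int is low in dup_161_KD alone and SLC7A11 and CYP51A1 are lowest in dup_2477_KD.

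Of 70 members tested from the 8-cell and DUX4 target list, 61 fell, 1 rose and 8 did not pass; adjusted over the list alone, 62 fell and 1 rose. The median log2 fold change was -2.20 (camera adjusted p = 1.73e-90, adjusted p = 0.0334 with an estimated correlation). Members named by the rule, for a small p or for abundance, included SLC34A2 (-2.57), RFPL4B (-3.03), the meiotic cyclin CCNA1 (-2.54) and the alkaline phosphatase ALPG (-2.09). The member that rose was FAM151A (0.58), named after its value was seen. Among naive pluripotency genes, 14 of 23 fell, 1 rose and 8 did not pass, with KLF17 at -2.96 and ALPP at -2.05. The naive median was -1.17 and was -0.73 without Ctrl_KD replicate 2 (camera adjusted p = 7.4e-14, adjusted p = 0.136 with an estimated correlation).

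Primed pluripotency genes split, with 14 of 31 higher, 11 lower and 6 not passing, and the list as a whole did not pass (15 higher and 11 lower over the list alone, adjusted p = 0.592); its median was 0.04 and its mean -0.15. LEFTY1 and LEFTY2, secreted inhibitors of Nodal signalling, fell by 2.71 and 2.20, and FGF2, a growth factor that maintains primed cells, fell by 0.79. LIN28A, an RNA-binding protein of pluripotent cells, rose by 0.55. PODXL, a surface glycoprotein, fell by 0.60, and CD24 had 0.03 (adjusted p = 0.479). Mesendoderm and endoderm markers had 7 of 18 lower, 4 higher and 7 not passing (4 higher and 8 lower over the list alone, adjusted p = 0.00703, adjusted p = 0.188 with an estimated correlation). Lower were CER1, a secreted inhibitor of Nodal and BMP (-3.99), CXCR4, a chemokine receptor (-2.97), and EOMES, a T-box factor of the primitive streak (-2.27). The median of this list was -0.75, and was -0.19 without Ctrl_KD replicate 2. It was -1.20 with a minimum of 1 CPM, and without a filter on low counts the call was lost (adjusted p = 0.0557, range over the alternatives 0.000922 to 0.0557).

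Of 28 p53 targets, 21 rose, 2 fell and 5 did not pass (median 0.63, adjusted p = 4.55e-16, adjusted p = 0.0728 with an estimated correlation). The antiproliferative gene BTG2 rose from 5.191 to 37.95 CPM (log2 2.87), FDXR, a mitochondrial reductase, rose by 1.90, and PLK2, a kinase, fell by 1.51. Immediate early genes fell in 18 of 21 cases, with 2 higher and 1 not passing (median -1.03, adjusted p = 2.06e-18, adjusted p = 0.0728 with an estimated correlation). MYC, a growth-promoting transcription factor, fell from 102.7 to 22.2 CPM, and CCN1, a matricellular protein, fell by 1.80. Cell cycle genes rose in 25 of 34 cases, with 3 lower and 6 not passing (26 higher and 3 lower over the list alone, median 0.39, adjusted p = 2.04e-09, adjusted p = 0.238 with an estimated correlation). They included the topoisomerase TOP2A (0.80), the thymidylate synthase TYMS (0.85) and the replication clamp PCNA (0.74).

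Integrated stress response genes had 13 of 28 lower, 7 higher and 8 not passing, or 14 and 8 adjusted over the list alone (adjusted p = 0.000224, adjusted p = 0.188 with an estimated correlation). The amino acid transporter SLC7A5 fell by 0.98, the pseudokinase TRIB3 by 1.78 and the mTOR inhibitor DDIT4 by 1.16. Glycolysis and hypoxia genes had 17 of 32 lower, 4 higher and 11 not passing (5 higher and 18 lower over the list alone, adjusted p = 1.12e-05, adjusted p = 0.188 with an estimated correlation). Among them the peptide hormone ADM fell by 1.38, and the glycolytic regulators HK2 and PFKFB3 each fell by 1.07. Nuclear genes of oxidative phosphorylation rose in 24 of 45 cases, with 2 lower and 19 not passing (24 higher and 3 lower over the list alone, adjusted p = 0.00966, adjusted p = 0.322 with an estimated correlation), including SDHA (0.56) and COX7C (0.40). Heterogeneous nuclear ribonucleoproteins, which bind nascent RNA, had 17 of 26 higher, 1 lower and 8 not passing (17 higher and 2 lower over the list alone, adjusted p = 0.00278, adjusted p = 0.584 with an estimated correlation). HNRNPDL rose by 0.45, HNRNPA2B1 rose by 0.39 and HNRNPUL1 fell by 0.55, while HNRNPU had 0.02 (adjusted p = 0.666). Retroelement repression genes had 13 of 30 higher, 6 lower and 11 not passing (14 higher and 6 lower over the list alone, adjusted p = 0.00735, adjusted p = 0.677 with an estimated correlation), with the H3K9 methylation cofactor ATF7IP at 0.55 and the DNA methyltransferase DNMT3B at 0.40.

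Fibroblast markers rose in 9 of 14 cases, with 2 lower and 3 not passing (median 0.58, adjusted p = 3.26e-06, adjusted p = 0.171 with an estimated correlation). COL1A2 rose by 2.17 and fibronectin FN1 by 1.00, while TAGLN, an actin-binding protein, fell by 1.32. Trophoblast and neuroectoderm markers did not pass as lists. Trophoblast markers had 9 of 17 higher, 3 lower and 5 not passing (adjusted p = 0.343), with the keratins KRT7 at 1.60 and KRT8 at -0.46 and the factor TFAP2C at -1.17. VGLL1 and ELF5, trophoblast regulators with 0 counts in Ctrl_KD, had 22 and 14 counts. These were 6.78- and 4.32-fold higher with Ctrl_KD at a floor of 3 counts over the group, without counting error of the 22 and 14. Neuroectoderm markers had 5 of 13 higher, 3 lower and 5 not passing (adjusted p = 0.726), with the intermediate filament NES at -0.67, the neuronal protein DCX at 2.34 and the forebrain factor SIX3 at 2.57.

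Several further lists had no call as a whole. Of these, interferon response (adjusted p = 0.0304), ribosomal protein (0.000187) and mitochondrially encoded genes (0.0316) passed without a filter on low counts, as did trophoblast markers (0.0365). By fry, heat shock genes (adjusted p = 0.0409) and RNA polymerase II genes (0.0374) passed, as did primed pluripotency genes (0.00713) and trophoblast markers (0.0175). Heat shock genes had 5 of 15 higher, 5 lower and 5 not passing (adjusted p = 0.358), with the chaperones HSPA1A at -1.16 and HSPA1B at -1.07 and SERPINH1 at 0.48. Interferon response genes had 3 of 26 higher, 13 lower and 10 not passing (adjusted p = 0.625), with the antiviral genes BST2 at 1.84, TRIM22 at 1.33 and IFIT1 at -2.71. Ribosomal protein genes had 27 of 77 higher, 7 lower and 43 not passing (adjusted p = 0.153), with RPL13A at 0.43, RPL15 at 0.33 and RPLP1 at -0.32. Mitochondrially encoded genes had 5 of 13 higher, 2 lower and 6 not passing (7 higher and 2 lower over the list alone, adjusted p = 0.343), with MT-CO3 at 0.26, MT-ND4L at 0.15 and MT-CYB at 0.24, or 0.13 without Ctrl_KD replicate 2. By limma on log2 TPM with a pseudocount of 1, MT-CYB (adjusted p = 0.0862) and MT-ND4L (0.0659) were not called. Cholesterol genes had 8 of 24 higher, 9 lower and 7 not passing (adjusted p = 0.612, median above 0 and mean below), with HMGCS1 at -0.67 and INSIG1 at -0.68. RNA polymerase II genes had 10 of 33 higher, 10 lower and 13 not passing (adjusted p = 0.612, median above 0 and mean below), with GTF2F1 at -0.96, TAF10 at -0.48 and TAF1 at -0.52.

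The largest rises after dup_161 knockdown were in genes with little RNA in Ctrl_KD. SST, the hormone somatostatin (chromosome 3, 187668906 to 187670399), rose from 0.2091 to 5.382 CPM (log2 4.68, SE 0.30, adjusted p = 3.17e-14). The others were the adhesion gene CTNNA3 (4.17), the T-box gene TBX10 (4.12), SYNDIG1L (3.78), the reductase DHRS2 (3.57), the synaptic gene CPLX2 (3.42), and the cartilage genes COL2A1 (3.38) and HAPLN1 (3.08).

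Among repeats, MLT2A1 fell from 161.2 ± 3.27 to 59.56 ± 0.567 CPM (log2 -1.44, SE 0.05, adjusted p = 2.13e-21), MLT2A2 fell by 0.63 and HERVL-int, the internal part of the related retrovirus, fell by 0.84. The MLT2 and ERVL list had 10 of 23 lower, 0 higher and 13 not passing (0 higher and 11 lower over the list alone, adjusted p = 1.19e-05, adjusted p = 0.216 with an estimated correlation). HERVK-int and its LTR, LTR5_Hs, fell by 1.21 and 0.83, and LSAU, a satellite of the DUX4 array, fell by 4.40. HERV9NC-int (1.10), HERVI-int (1.68), MER61-int (0.48) and the LINE-1 subfamily L1PA2 (0.39) rose. THE1, MST and MLT1 elements had 17 of 26 lower, 1 higher and 8 not passing (adjusted p = 0.00707, adjusted p = 0.751 with an estimated correlation). The remaining repeat lists did not pass: HERVH and HERVK had 7 of 25 higher and 7 lower (7 higher and 8 lower over the list alone, adjusted p = 0.593, median and mean below 0, direction of the test up), young LINE-1, SVA and AluY had 2 of 21 higher and 10 lower (2 higher and 12 lower over the list alone, adjusted p = 0.634), and satellites had 0 of 17 higher and 5 lower (adjusted p = 0.685). Without Ctrl_KD replicate 1 the satellite list passed (adjusted p = 0.0418, range over the alternatives 0.0418 to 0.854). The count of 389 repeats called was 211 without dup_161_KD replicate 1, 255 without dup_161_KD replicate 2 and 234 without Ctrl_KD replicate 2. On log2 TPM with a pseudocount of 1 it was 5 by limma, and HERV9NC-int and LTR5_Hs were then not called.

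Knockdown of dup_2477 asked the same question for another copy, with the same controls. DUX4 fell further, to 1.423 ± 0.261 CPM, 99.2-fold below Ctrl_KD, and the 8-cell genes and MLT2A1 fell again. Cholesterol biosynthesis genes (adjusted p = 0.0775 with an estimated correlation) and stress response genes (adjusted p = 0.023 with an estimated correlation) were lower as well: the sterol demethylase CYP51A1 fell from 122.6 to 56.59 CPM, and the cystine transporter SLC7A11 fell from 241.9 to 58.67 CPM. BTG2 rose from 5.191 to 75.27 CPM, and most genes of cytosolic ribosomal proteins were slightly higher (adjusted p = 0.157 with an estimated correlation). Of 26964 genes, 5778 were higher and 6410 lower (45.2% together), of which 1754 and 1167 differed by at least 2-fold; 115 repeats were higher and 232 lower.

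The log2 fold change of DUX4 was -6.63 (SE 0.10, adjusted p = 9.72e-29), and the summed DUX4 and DUX4L genes were 63-fold lower. DUX4L2 (-8.56), DUX4L7 (-8.02), DUX4L12 (-7.69), DUX4L8 (-5.45) and DUX4L20 (-5.38) fell. DBET had 9 counts and DUX4L22 had 3. Of the 70 genes of the 8-cell list, 59 fell, 0 rose and 11 did not pass, or 61 and 0 adjusted over the list alone. The list median was -1.99 (adjusted p = 8.64e-73, adjusted p = 0.023 with an estimated correlation). SLC34A2 fell by 2.19, RFPL4B by 2.73, RFPL2 by 2.79, CCNA1 by 1.77 and ALPG by 1.62. Naive pluripotency genes had 14 of 23 lower, 5 higher and 4 not passing (median -0.74, adjusted p = 6.51e-07, adjusted p = 0.157 with an estimated correlation), with KLF17 at -2.54 and ALPP at -1.29. Primed pluripotency genes had 19 of 31 higher, 9 lower and 3 not passing, and the list did not pass (adjusted p = 0.295, median 0.20, mean -0.03). LEFTY1 fell by 3.10, LEFTY2 by 2.88, PODXL by 0.28 and FGF2 by 0.29, and DNMT3B rose by 0.59, CD24 by 0.36 and LIN28A by 0.34.

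**Figure D2:**
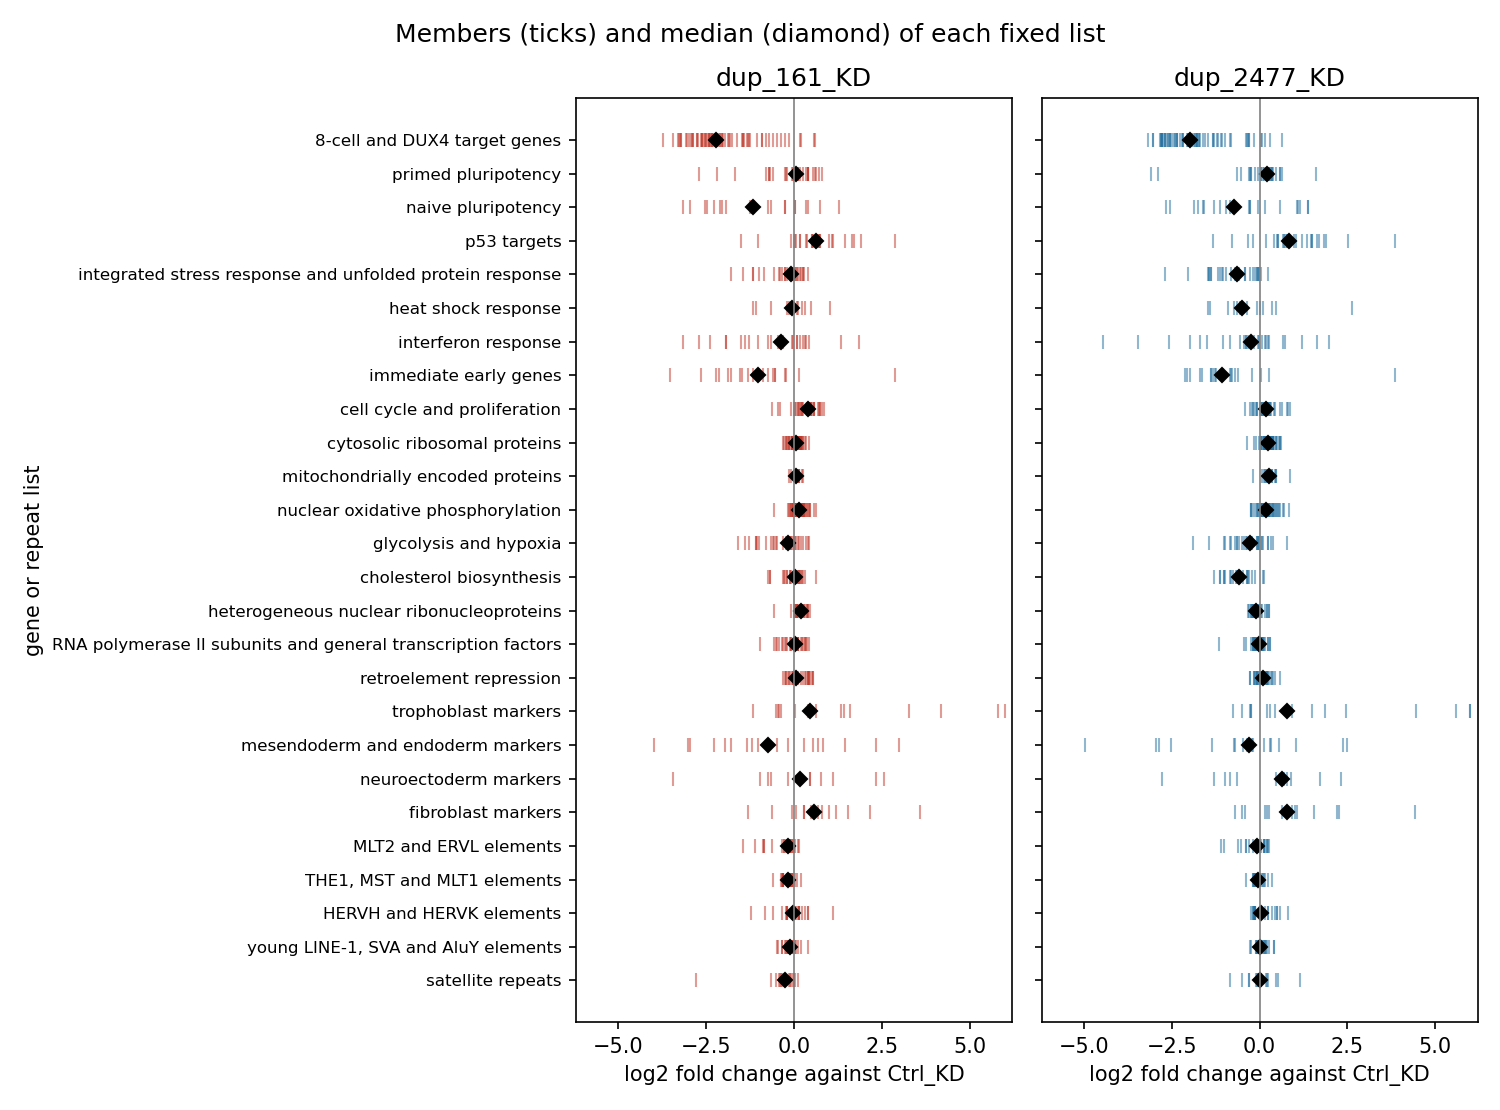
Log2 fold change against Ctrl_KD of each tested member (ticks) and the median (diamond) of the 26 gene and repeat lists, for dup_161_KD on the left and dup_2477_KD on the right, with values beyond 6 drawn at 6. The 8-cell medians lie at -2.20 and -1.99, and the cholesterol median lies at 0.03 and -0.60.

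Of the cholesterol biosynthesis genes, 22 of 24 fell, 0 rose and 2 did not pass, with 22 lower and 1 higher adjusted over the list alone (median -0.60, adjusted p = 9.8e-21, adjusted p = 0.0775 with an estimated correlation). The synthase LSS fell by 0.99, CYP51A1 fell by 1.12, the sterol sensor INSIG1 fell by 1.12 and the synthase HMGCS1 fell by 0.83. Integrated stress response genes had 20 of 28 lower, 1 higher and 7 not passing (median -0.66, adjusted p = 1.11e-30, adjusted p = 0.023 with an estimated correlation), with SLC7A11 at -2.04, SLC7A5 at -1.44, TRIB3 at -2.70 and DDIT4 at -1.39. Heat shock genes had 9 of 15 lower, 3 higher and 3 not passing (median -0.51, adjusted p = 3.34e-06, adjusted p = 0.157 with an estimated correlation). HSPA1B fell by 1.48, HSPA1A by 1.42 and the constitutive chaperone HSPA8 by 0.57.

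The p53 targets had 23 of 28 higher, 4 lower and 1 not passing (median 0.82, adjusted p = 1.42e-35, adjusted p = 0.023 with an estimated correlation), with BTG2 at 3.86, FDXR at 2.50 and the cell cycle inhibitor CDKN1A 2.83-fold higher. Immediate early genes had 18 of 21 lower, 2 higher and 1 not passing (median -1.07, adjusted p = 3.59e-15, adjusted p = 0.0459 with an estimated correlation). MYC fell by 2.07 and JUN, a subunit of the AP-1 factor, by 1.69. Cell cycle genes had 20 of 34 higher, 5 lower and 9 not passing (22 higher and 5 lower over the list alone, adjusted p = 0.000194, adjusted p = 0.34 with an estimated correlation), with TOP2A at 0.77, TYMS at 0.87 and the helicase subunit MCM6 at 0.81.

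Ribosomal protein genes rose in 66 of 77 cases, with 1 lower and 10 not passing (67 higher and 1 lower over the list alone, median 0.23, adjusted p = 1.2e-11, adjusted p = 0.157 with an estimated correlation), including RPL13A (0.59), RPL41 (0.60) and RPS25 (0.55). Mitochondrially encoded genes rose in 11 of 13 cases, with 1 lower and 1 not passing (median 0.25, adjusted p = 6.85e-05, adjusted p = 0.333 with an estimated correlation), with MT-ND3 at 0.85, MT-ND2 at 0.47 and MT-ND1 at 0.47. Oxidative phosphorylation genes had 24 of 45 higher, 5 lower and 16 not passing (25 higher and 5 lower over the list alone, adjusted p = 0.000508, adjusted p = 0.157 with an estimated correlation), with COX7C at 0.70, SDHA at 0.67 and ATP5F1A at 0.41. Glycolysis and hypoxia genes had 18 of 32 lower, 5 higher and 9 not passing (5 higher and 19 lower over the list alone, adjusted p = 5.17e-06, adjusted p = 0.157 with an estimated correlation), with ADM at -1.45, the glucose transporter SLC2A3 at -0.82 and the pyruvate kinase PKM at -0.70.

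Fibroblast markers had 11 of 14 higher, 2 lower and 1 not passing (median 0.78, adjusted p = 1.34e-12, adjusted p = 0.0741 with an estimated correlation), with COL1A2 at 1.55, COL6A3 at 2.20 and the smooth muscle actin ACTA2 at 2.27. Trophoblast markers had 10 of 17 higher, 3 lower and 4 not passing (adjusted p = 0.048, adjusted p = 0.192 with an estimated correlation), with the nuclear receptor NR2F2 48.4-fold and KRT7 2.84-fold higher and KRT18 at -0.49. VGLL1 and ELF5 had 24 and 21 counts against 0 in Ctrl_KD, 7.39- and 6.47-fold higher with Ctrl_KD at the floor. The list median of 0.77 (1.7-fold) could not move with both at those values, since they still lay above it. The list mean fell from 1.73 to 1.30. The trophoblast call was lost with a minimum of 1 CPM (adjusted p = 0.112), with GC and length offsets chosen after seeing the data (0.0631), and without Ctrl_KD replicate 1 (0.0674), dup_2477_KD replicate 1 (0.0703) or dup_2477_KD replicate 2 (0.0796); the range over the alternatives was 0.0088 to 0.112. Mesendoderm and endoderm markers had 4 of 18 lower, 3 higher and 11 not passing (adjusted p = 0.00782, adjusted p = 0.157 with an estimated correlation), with CER1 at -4.96, CXCR4 at -2.85 and EOMES at -2.94. Their median was -0.29, but 0.03 without Ctrl_KD replicate 2 and -0.50 without Ctrl_KD replicate 1, and the call was lost without a filter on low counts (adjusted p = 0.177, range over the alternatives 0.000522 to 0.177).

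The remaining gene lists did not pass by camera. By fry, neuroectoderm markers (adjusted p = 0.00239) and RNA polymerase II genes (0.0151) passed with direction down. Primed pluripotency genes passed by fry with direction up (adjusted p = 0.00471). Interferon genes had 7 of 26 higher, 11 lower and 8 not passing (7 higher and 13 lower over the list alone, adjusted p = 0.7, median and mean below 0, direction of the test up), with BST2 at 1.98, TRIM22 at 1.63 and IFIT1 at -2.57. Neuroectoderm markers had 5 of 13 higher, 4 lower and 4 not passing (adjusted p = 0.416, median 0.64 or 0.41 without Ctrl_KD replicate 2, mean 0.12, direction of the test down), with NES at -0.85, the tubulin TUBB3 at -0.65 and MAP2 at -1.29. Heterogeneous nuclear ribonucleoproteins had 14 of 26 lower, 5 higher and 7 not passing (adjusted p = 0.295), with HNRNPM at -0.34, PCBP1 at -0.30, HNRNPAB at -0.26 and HNRNPU at -0.23 (adjusted p = 4.35e-06). RNA polymerase II genes had 9 of 33 lower, 4 higher and 20 not passing (adjusted p = 0.416), with GTF2F1 at -1.15, TAF10 at -0.38 and GTF2H2 at -0.43. Retroelement repression genes had 13 of 30 higher, 4 lower and 13 not passing (adjusted p = 0.0646), with CBX1 at 0.43. That list passed without Ctrl_KD replicate 1 (adjusted p = 0.0391), without dup_2477_KD replicate 2 (0.0105), without a filter on low counts (0.0226) and with RLE size factors (0.047), and the range over the alternatives was 0.0105 to 0.165. Without a filter on low counts, primed pluripotency genes (adjusted p = 0.0126) and heterogeneous nuclear ribonucleoproteins (0.0191) passed too.

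Of the largest rises, NR2F2 (chromosome 15, 96325938 to 96340263) went from 0.1059 to 5.14 CPM (48.4-fold, adjusted p = 7.82e-15). The inositol kinase IP6K3 (4.48), FRMPD2 (4.40), the glycosyltransferase CSGALNACT1 (4.14), LGI1 (3.96), BTG2 (3.86), the WNT inhibitor FRZB (3.63) and HAPLN1 (3.62) followed.

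MLT2A1 fell to 75.75 ± 0.927 CPM (log2 -1.09, SE 0.045, adjusted p = 3.3e-18), MLT2A2 fell by 0.39 and HERVL-int by 0.62. LSAU (-4.24), L1M8 (-0.94) and MLT1E3 (-0.78) fell, and HERVI-int (1.65), HERV9NC-int (0.81), HERVH-int (0.50) and MER61-int (0.71) rose. The MLT2 and ERVL list had 7 of 23 lower, 5 higher and 11 not passing (5 higher and 8 lower over the list alone, adjusted p = 0.0131, adjusted p = 0.34 with an estimated correlation). That call was lost without dup_2477_KD replicate 1 (adjusted p = 0.21), without either dup_161_KD library (0.183 and 0.176) and without a filter on low counts (0.177); the range over the alternatives was 0.0112 to 0.21. HERVH and HERVK elements had 7 of 25 higher, 4 lower and 14 not passing (8 higher and 8 lower over the list alone, adjusted p = 0.00197, adjusted p = 0.157 with an estimated correlation). Young LINE-1, SVA and AluY elements had 6 of 21 higher and 2 lower (7 higher and 3 lower over the list alone, adjusted p = 0.071), THE1, MST and MLT1 elements 4 of 26 higher and 7 lower (4 higher and 8 lower over the list alone, adjusted p = 0.93), and satellites 3 of 17 higher and 3 lower (adjusted p = 0.93). The LINE-1, SVA and AluY list passed without Ctrl_KD replicate 2 (adjusted p = 0.00753) and without dup_2477_KD replicate 2 (0.0441), and the range over the alternatives was 0.00753 to 0.348. On log2 TPM with a pseudocount of 1, limma called 8 repeats, HERV9NC-int not among them, and 3735 genes higher.

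The knockdowns shared much of their response. Of the genes tested, 3549 were higher in both, against 1242 expected from independent calls, and 3853 were lower in both, against 1383 expected; 601 were called in opposite directions. Fold changes of the 2 knockdowns correlated at 0.765 across genes, which are not independent replicates. In 40 simulations, all 6 libraries were drawn without group differences, and both simulated knockdowns were compared with the same 2 simulated control libraries. No gene was called in both. Since no change was simulated, this cannot tell whether differences between the real control and knockdown cultures lie behind the shared calls. The correlation averaged 0.509 in the simulations, where only the shared controls produce it, so it is not comparable with 0.765. The covariance can be compared and was 0.566 in the data and 0.0389 in the simulations. At the simulated spread between libraries, the shared controls thus carry a small part of the covariance.

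**Figure D3:**
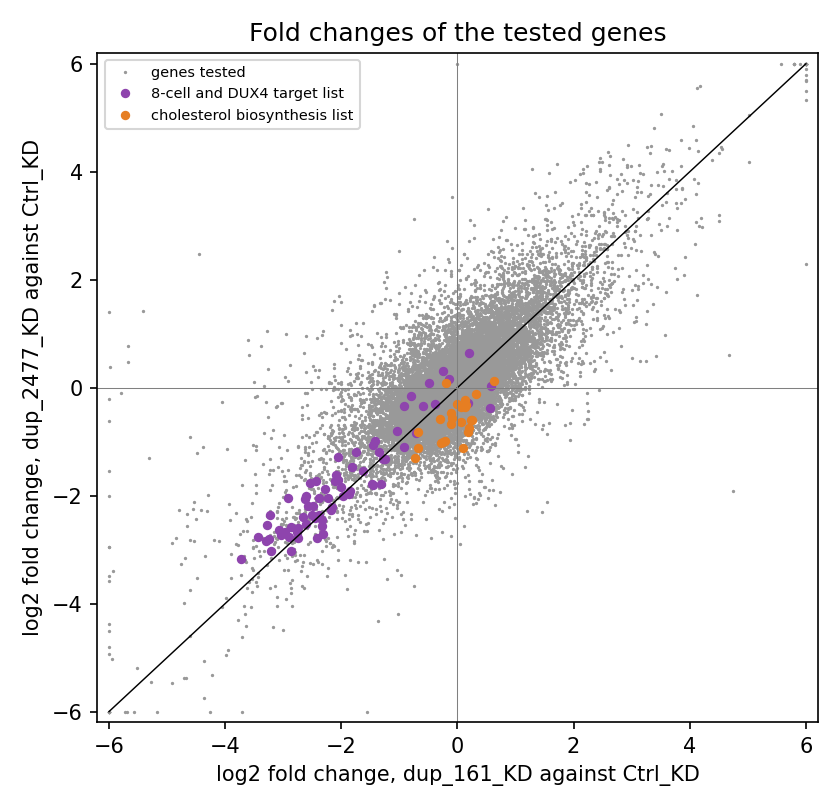
Log2 fold change of each tested gene in dup_2477_KD (vertical) against dup_161_KD (horizontal), both relative to Ctrl_KD, with the diagonal marking equal change and values beyond 6 drawn at 6. The 8-cell list (purple) lies low on both axes, with medians of -2.20 and -1.99, and the cholesterol list (orange) lies below the diagonal, with a direct median difference of 0.50.

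The direct contrast of dup_161_KD with dup_2477_KD asked where the knockdowns differed. It did not use the Ctrl_KD means, but the Ctrl_KD libraries were part of the fit. Cholesterol and stress response genes were higher in dup_161_KD than in dup_2477_KD, although both list calls were lost when the correlation was estimated (adjusted p = 0.102 and adjusted p = 0.0801 with an estimated correlation). SLC7A11 was 5.04-fold higher and CYP51A1 2.31-fold higher. Ribosomal protein genes were lower in dup_161_KD (adjusted p = 0.232 with an estimated correlation), as was HERVK-int, at 270.5 against 574.5 CPM. Of 26964 genes, 4836 were higher in dup_161_KD and 4511 lower (34.7% together), 340 and 837 of them by at least 2-fold; 50 repeats were higher and 175 lower. DUX4 was higher in dup_161_KD (log2 0.91, SE 0.17, adjusted p = 6.34e-05), while MLT2A1 was lower (-0.35, SE 0.05, adjusted p = 1.73e-06).

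Of the cholesterol genes, 23 of 24 were higher and 1 lower (median 0.50, adjusted p = 2.13e-35, adjusted p = 0.102 with an estimated correlation), with CYP51A1 at 1.21 and LSS at 0.77. Integrated stress response genes had 24 of 28 higher, 1 lower and 3 not passing (median 0.37, adjusted p = 7.71e-28, adjusted p = 0.0801 with an estimated correlation), with SLC7A11 at 2.33 and TRIB3 at 0.92. Heat shock genes had 12 of 15 higher, 2 lower and 1 not passing (adjusted p = 4.79e-07, adjusted p = 0.232 with an estimated correlation), with HSPA8 at 0.54. Heterogeneous nuclear ribonucleoproteins had 22 of 26 higher, 1 lower and 3 not passing (24 higher and 1 lower over the list alone, median 0.23, adjusted p = 1.46e-09, adjusted p = 0.261 with an estimated correlation), with HNRNPU at 0.25 and HNRNPM at 0.36. Cell cycle genes had 20 of 34 higher, 3 lower and 11 not passing (adjusted p = 0.00198, adjusted p = 0.406 with an estimated correlation).

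Other lists were lower in dup_161_KD. Ribosomal protein genes had 60 of 77 lower, 1 higher and 16 not passing, or 64 and 1 adjusted over the list alone (median -0.18, adjusted p = 7.28e-13, adjusted p = 0.232 with an estimated correlation), with RPS25 at -0.41. Mitochondrially encoded genes had 10 of 13 lower, 2 higher and 1 not passing (adjusted p = 0.000109, adjusted p = 0.346 with an estimated correlation), with MT-ND3 at -0.81. The p53 targets had 17 of 28 lower, 3 higher and 8 not passing, or 20 and 3 adjusted over the list alone (median -0.24, adjusted p = 3.74e-10, adjusted p = 0.108 with an estimated correlation), with BTG2 at -0.99. The 8-cell list had 21 of 70 lower, 3 higher and 46 not passing (median -0.24, adjusted p = 0.00256, adjusted p = 0.335 with an estimated correlation), with CCNA1 at -0.76 and SLC34A2 at -0.39. Naive pluripotency genes had 13 of 23 lower, 1 higher and 9 not passing (adjusted p = 0.00047, adjusted p = 0.303 with an estimated correlation). Fibroblast markers had 8 of 14 lower, 2 higher and 4 not passing (adjusted p = 0.00116, adjusted p = 0.232 with an estimated correlation), with ACTA2 at -1.07 and COL1A2 at 0.62. Primed pluripotency genes had 15 of 31 lower, 11 higher and 5 not passing (11 higher and 16 lower over the list alone, adjusted p = 0.0115, adjusted p = 0.261 with an estimated correlation); without a filter on low counts the call was lost (adjusted p = 0.176, range over the alternatives 0.00384 to 0.176).

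The gene lists without a call between the knockdowns were interferon response (6 of 26 lower, 3 higher, adjusted p = 0.182), immediate early genes (8 of 21 higher, 8 lower, 9 higher and 9 lower over the list alone, adjusted p = 0.156, median above 0 and mean below), oxidative phosphorylation (16 of 45 lower, 7 higher, 8 higher and 16 lower over the list alone, adjusted p = 0.25) and glycolysis (12 of 32 higher, 8 lower, adjusted p = 0.9, median above 0 and mean below). RNA polymerase II genes (10 of 33 higher, 5 lower, adjusted p = 0.776), retroelement repression (10 of 30 higher, 6 lower, 12 higher and 7 lower over the list alone, adjusted p = 0.25) and trophoblast markers (5 of 17 lower, 2 higher, adjusted p = 0.175) did not pass either. The same held for mesendoderm markers (4 of 18 higher, 1 lower, adjusted p = 0.989) and neuroectoderm markers (4 of 13 higher, 2 lower, adjusted p = 0.104). By fry, immediate early genes (adjusted p = 0.0242), trophoblast markers (0.0242) and neuroectoderm markers (0.00318) passed. Retroelement repression genes passed without dup_2477_KD replicate 1 (adjusted p = 0.0314) and without a filter on low counts (0.0174), and neuroectoderm markers passed with a minimum of 1 CPM (0.0466).

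The genes with the largest direct differences upward were SST (4.07), CPLX2 (2.83), the neuropeptide precursor VGF (2.82), XKR7 (2.61), DHRS2 (2.60) and TBX10 (2.40). VGF (chromosome 7, 101162509 to 101165593) stood at 427 CPM in Ctrl_KD, 669.6 in dup_161_KD and 95.08 in dup_2477_KD. Downward they were FAM71F1 (-3.03), the tight junction gene CLDN11 (-2.55), the transcription factor POU2F3 (-2.53), the troponin TNNC2 (-2.47), CSGALNACT1 (-2.42) and the skeletal actin ACTA1 (-2.31).

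HERVK-int (log2 -1.09, SE 0.04, adjusted p = 3.42e-19), LTR5_Hs (-0.70), LTR72 (-1.38) and HERV4_I-int (-0.64) were lower in dup_161_KD, and LTR41B (0.75), Arthur1A (0.63), MER34B-int (0.32) and HERV9NC-int (0.29) were higher. MLT2A2 (-0.24) and HERVL-int (-0.21) were lower. The MLT2 and ERVL list had 10 of 23 lower, 0 higher and 13 not passing (0 higher and 11 lower over the list alone, adjusted p = 0.00478, adjusted p = 0.346 with an estimated correlation), and THE1, MST and MLT1 elements had 15 of 26 lower and 0 higher (0 higher and 18 lower over the list alone, adjusted p = 0.000123, adjusted p = 0.417 with an estimated correlation). Young LINE-1, SVA and AluY elements had 8 of 21 lower and 0 higher (0 higher and 10 lower over the list alone, adjusted p = 0.000872, adjusted p = 0.399 with an estimated correlation), and satellites had 6 of 17 lower and 1 higher (1 higher and 7 lower over the list alone, adjusted p = 0.508). HERVH and HERVK elements had 7 of 25 lower and 3 higher (3 higher and 10 lower over the list alone, adjusted p = 0.000749, adjusted p = 0.232 with an estimated correlation); the call was lost without dup_161_KD replicate 1 (adjusted p = 0.103, range over the alternatives 0.000386 to 0.103) and without a filter on low counts (0.0879). The count of 225 repeats was 96 without dup_161_KD replicate 1 and 130 without dup_161_KD replicate 2. On log2 TPM, where 217 repeats reached the minimum, limma called 0, and 169 were called by DESeq2 on counts. At an unadjusted p under 0.05 limma had 11, about as many as 217 tests would give without any change. Because limma estimated the spread over genes and repeats of like TPM together, this count cannot decide whether repeats changed. HERVK-int had an adjusted p of 0.0948 by limma with a pseudocount of 1 and 0.0661 with 0.1.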

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

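RLE size factors and scaling from genes alone were fixed as alternatives before the data were examined, and their use here and the other tests of explanations were chosen after the results were seen. Of the 140 named genes and repeats, 10 moved in opposite directions in the 2 knockdowns, each past the threshold against Ctrl_KD and in the direct contrast of dup_161_KD with dup_2477_KD.

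Higher in dup_161_KD by that contrast were VGF (log2 difference 2.82), XKR7 (2.61), SLC7A11 (2.33), TUBB3 (0.81), the repeat LTR41B (0.75) and HNRNPAB (0.43). Lower were MT-ND1 (-0.56), RPLP1 (-0.565), MT-ND2 (-0.61) and ACTA1 (-2.31). Over all genes tested, 601 moved in opposite directions in this way, and 5 repeats did.

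The 8-cell genes and MLT2A1 were lower together with DUX4 in both knockdowns. Reads reassigned among the 42 DUX4 and DUX4L genes do not account for the loss of DUX4 RNA, since their sum was still at least 47.1-fold lower. Reads shared among copies and left uncounted are not covered by that sum, because the treatment of reads with several alignments is not known. Whether the DUX4 RNA left over sets the 8-cell level stays open: DUX4 was higher in dup_161_KD (0.91) and the 8-cell median lower there (-0.24), but 46 of 70 members did not pass and adjusted p = 0.335 with an estimated correlation. Weaker induction of DUX4 in the knockdown cultures, whatever its origin, stays open too, because the highest DUX4 level in a knockdown library was 2.92 CPM and no library combined knockdown with high DUX4. An effect of the MLT2A1 copies on 8-cell genes therefore cannot be told apart from an effect that runs through DUX4 RNA.

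HERVK-int and LTR5_Hs fell mainly in dup_161_KD. The direct difference of HERVK-int had a weakest value of -1.09 over RLE size factors and scaling from genes alone, so the choice among these scalings does not explain it. Those scalings put the median of all genes at -0.006, and a scale error common to all of them was not tested. By limma on log2 TPM the difference was -0.73 (adjusted p = 0.0948) with a pseudocount of 1 and -1.01 (adjusted p = 0.0661) with 0.1, and neither was called. Whether a few copies or host transcripts carry the fall stays open: LTR5_Hs differed by -0.70, but copies are not resolved. An effect particular to the dup_161 ASO remains untested.

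Cholesterol biosynthesis genes were lower in dup_2477_KD than in dup_161_KD, a call that was lost with an estimated correlation (adjusted p = 0.102). After offsets for GC content and length the median difference was 0.49, so these trends do not explain it. Its lowest value over RLE size factors and scaling from genes alone was 0.49, so the choice among these scalings does not explain it. Those scalings put the median of all genes at -0.006, against -0.00052 in the main fit, and could hardly have moved the list. A scale error common to all of them was not tested. Medium or cell density that differed between the cultures may contribute and cannot be told apart from the ASO, since the labels give neither per culture; the libraries of a group differed by at most 0.031. An effect of the dup_2477 copy itself was not tested.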

How the results depend on the processing

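The GC and length offsets were chosen after seeing the data; the other alternatives were fixed before. A minimum fold of 2 left 1298 genes higher, 1522 lower and 19 repeats for dup_161_KD against Ctrl_KD, 1754, 1167 and 14 for dup_2477_KD against Ctrl_KD, and 340, 837 and 5 for the direct contrast, by construction. With limma on log2 TPM and a pseudocount of 1 or 0.1, repeats fell to 5 and 4, to 8 and 8, and to 0 and 0 in those comparisons. At an unadjusted p under 0.05 the direct contrast had 11, about as many as 217 tests would give without any change. The spread was estimated over genes and repeats of like TPM together, so this count cannot decide whether repeats changed. On counts, edgeR called 225 there and DESeq2 169. Only 217 of 1133 repeats reached the TPM minimum; what else lowered the counts was not tested. Genes higher in dup_2477_KD were then 3735 and 3722, and genes lower in the direct contrast 2546 and 2508. TMM factors were not applied to TPM. The median log2 fold change of all genes was -0.051 and -0.061 for dup_2477_KD, against -0.00997 by edgeR. In the direct contrast it was 0.029 and 0.035, against -0.00052. Whether this shift lowered the counts was not tested. Leaving out each library gave 211 to 441 repeats for dup_161_KD against Ctrl_KD (211, 255 and 234 without dup_161_KD replicates 1 and 2 and Ctrl_KD replicate 2) and 96 to 228 for the direct contrast (96 and 130 without dup_161_KD replicates 1 and 2), with fewer libraries in the fit; a lone library was assumed to vary like the others. With an estimated correlation 1, 4 and 0 lists passed, in place of 14, 17 and 16. By fry 18, 20 and 18 lists passed.

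Every other count stayed within 1.5 times its value. With replicate number as a block, 5980 genes were higher and 5931 lower for dup_161_KD, 5895 and 6572 for dup_2477_KD, and 5053 and 4617 in the direct contrast, and trophoblast markers lost their call for dup_2477_KD (adjusted p = 0.0599) while young LINE-1, SVA and AluY elements gained theirs (adjusted p = 0.0386). Replicate numbers showed no pairing, with deviations of equally numbered libraries correlating at 0.027, 0.066 and 0.017 across genes. Of 3248 values of named genes and repeats, 3223 were counted as unchanged, 25 lost the call and 0 reversed a call. Values not called in the main fit were counted as unchanged when their sign differed, for lists too. Of 936 list values, 904 were kept, 15 lost and 17 gained a call, and 0 reversed a called direction of the test. All of these came from camera at the preset correlation in edgeR fits. DESeq2, limma on log2 TPM, the fits of 4 libraries and the estimated correlation are not among them. Depth limits genes near the floor of 3 counts, such as DBET.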

Other observations

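The groups in this part were picked, and all their tests chosen, after the data were examined, from 210 symbol families, chromosomes and gene types of at least 12 members. With an estimated correlation none of the tests of the families named here passed in any of the 3 comparisons, the lowest adjusted p being 0.597. Clustered histone genes, most of whose RNAs lack a polyA tail in dividing cells, were higher after dup_161 knockdown: 27 of 39 rose, 0 fell and 12 did not pass (median log2 fold change 1.25). The linker histone H1-2 rose by 3.02, the core histone H2AC6 by 3.01 and H4C14 by 1.34. In dup_2477_KD 11 rose and 2 fell, and in the direct contrast 18 were higher in dup_161_KD and 0 lower (median 0.74). Collagen genes, which build the extracellular matrix, rose in 22 and fell in 11 of 41 cases after dup_161 knockdown. They rose in 27 and fell in 6 after dup_2477 knockdown. The fixed lists hold 5 of these collagen genes. COL2A1 rose by 3.38 and 2.50 and COL5A2 by 1.69 and 1.54, while COL12A1 fell by 1.46 in dup_161_KD and had 0.12 (adjusted p = 0.0992) in dup_2477_KD.

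Protocadherin alpha genes, neuronal adhesion molecules, fell in 13 of 13 cases after dup_2477 knockdown (median -0.72), and 3 of 13 fell after dup_161 knockdown. PCDHA10 had -0.17 and -0.73 and PCDHA13 had -0.15 and -0.80; members share their last exons, so their counts are not independent. PRAMEF genes, expressed in the early embryo and 14 of them members of the 8-cell list, fell in 17 and 16 of 19 cases, with PRAMEF12 at -3.21 and -3.03. Of 16 KLF factors, 10 fell, 0 rose and 6 did not pass after dup_161 knockdown. After dup_2477 knockdown 9 fell, 3 rose and 4 did not pass. The fixed lists hold 5 of these KLF factors. KLF18 fell by 3.52 and 2.95 and KLF6 by 1.52 and 1.63, while KLF12 had -0.10 (adjusted p = 0.234) and -0.66.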
